A study of Homo sapiens with 5 samples.

How the data were processed

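MonoMac6, an established human cell line of monocytic origin, was cultured with an added eicosanoid or left unstimulated, and total RNA was hybridised to 1 GeneChip array per condition. The 5 arrays cover unstimulated cells and cells cultured with leukotriene B4, leukotriene C4, lipoxin A4 or lipoxin B4, each added at 100 nM from a DMSO stock for 12 h, per the labels. Whether the unstimulated cells received DMSO is not given in the sources used here. Groups were taken from the sample titles, and each group holds 1 array.

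The deposited values are intensity signals on a linear scale, 1 for each of 54675 probe sets per array. The authors used GCOS version 1.4, per the submitters' processing notes; the signal algorithm and its settings are not given in the sources used here. The mean of the deposited signals without the highest and lowest 2% of probe sets was 499.9 on every array, so each array had been scaled to a common mean before deposit. Detection calls were not used here. Of the 54675 probe sets, 62 are controls. In the platform annotation, 41097 probe sets carry 1 gene symbol, 1801 carry several and 11777 are not listed; genes were named only from probe sets with 1 symbol. For 41043 of these the gene identifier matched the current gene table (assembly GRCh38.p14), from which symbols and chromosomes were taken; 0 symbols were altered by this step.

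Signals were converted to log2, and each array was scaled by 1 factor so that the median over the upper 50% of probe sets, by mean signal, was equal on all arrays. Values under a floor, the 50th percentile of the probe sets' mean log2 signal (a signal of 48.7), were set to the floor. Probe sets above the floor on at least 1 array were called measured, 36763 in all, and 29424 of them had 1 symbol. Each of the 15374 measured genes was represented by its probe set of highest mean signal; 7536 genes had several measured probe sets, and where these disagreed in sign the gene was not named by rank. A gene was counted as higher or lower at a difference of at least 2-fold. Where 1 side lay under the floor, the difference is a bound against the floor and is written as at least N-fold.

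With 1 array per condition no test, p-value or standard error was computed. In their place, 5 yardsticks were used: the differences between all 10 pairs of arrays, the counts obtained with each array in turn as the reference, the 3 ways of splitting the 4 stimulated arrays into pairs, the spread between stimulated arrays among the 500 genes of nearest signal, and 100 simulations of 5 unchanged arrays. In these simulations each gene's residual was drawn from the stimulated arrays' residuals of genes of nearby signal, so that any real differences among the eicosanoids count as spread. The residuals were taken after the floor was set; a first version, which took them before, gave more 2-fold differences than any observed pair of arrays and was replaced. The counting was checked on simulated data in which 200 of 15374 genes were set higher on 1 stimulated array. Of genes set 2-fold higher, 47.7% of those with a mean signal under 200 and 49.1% of the others were counted as at least 2-fold higher. Of genes set 3-fold higher, the shares were 91.3% and 99.0%. Starting values were means of values already raised to the floor. The shares for dim genes therefore do not hold for rises that begin below the floor.

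Before the data were examined, 20 gene lists and 6 lists of markers of other cell types were fixed, together with the rule for named genes and the alternatives. For each list the median log2 difference was placed as a percentile among 10000 random lists of the same size, matched on mean signal by deciles; it describes these arrays only. Lists were also matched to the 100 genes nearest to each member by mean signal, which was chosen after seeing the data. Named genes were, per comparison, up to 8 with the largest difference each way among genes above the floor on both sides whose other measured probe sets did not have the opposite sign, up to 3 each way known only as a bound and backed by another probe set at least 2-fold apart, and up to 4 members of each list at least 2-fold apart. The rule as fixed asked for the same sign in all probe sets; a difference of 0, where both values lay at the floor, was let through, and other probe sets at 0 are given with the gene. For all 4 eicosanoids together the rank was by the smallest difference, and for the classes by the gap between the nearest arrays. The genes of leukotriene synthesis and the eicosanoid and formyl peptide receptors were always examined. Genes named outside this rule were chosen after their values were seen, and the text says so.

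The alternatives were a floor at the 30th percentile (signal 17.4), at the 70th percentile (signal 243) or at the 90th percentile of the values of other cell types' markers (signal 92.1, called the background floor), quantile normalization, the values as deposited, the mean of all probe sets of a gene, leaving out probe sets that may cross-hybridise, keeping only genes whose probe sets share 1 sign, and a 3-fold threshold. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The number of arrays limits the precision of every value.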

Results

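The series asks how mRNA levels of monocytic cells respond to eicosanoids that its title divides into pro- and anti-inflammatory ones. Leukotriene B4, a dihydroxy acid, and leukotriene C4, a glutathione conjugate, are products of the 5-lipoxygenase pathway, and lipoxins A4 and B4 are trihydroxy acids made by the combined action of lipoxygenases. MonoMac6 cells were cultured for 12 h with each of these 4 compounds at 100 nM, and each condition was read on 1 array beside 1 array of unstimulated cells. There were no replicates, so no difference below has a measured error, and all are differences between arrays.

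Signals of different probe sets depend on the affinity of their probes, so those of the eicosanoid pathway were set against the floor of 48.7 and not against each other. ALOX5AP, which presents arachidonic acid to 5-lipoxygenase, had a signal of 34319 on the unstimulated array, and LTA4H, the hydrolase that makes leukotriene B4, had 3681. ALOX5 itself had 143 on its brightest probe set, while its other 3 were under the floor on 3 to 5 of the 5 arrays, and LTC4S, the leukotriene C4 synthase, had 178. Among receptors, the leukotriene B4 receptor LTB4R (905) and the cysteinyl leukotriene receptor CYSLTR1 (1044) were well above the floor. CYSLTR2 (75.7) and the formyl peptide receptors FPR1 (70.9) and FPR2 (48.7), the last of which binds lipoxin A4, lay near it. LTB4R was lower on each stimulated array, by log2 differences between -0.36 and -0.47 on its brightest probe set, while its other probe sets gave between -0.07 and -0.21 and between 0.00 and 0.16. CYSLTR1 differed by at most 0.25 and LTA4H by at most 0.10. LTB4R2, which binds leukotriene B4 with lower affinity, had no probe set of its own here. Markers of other cell types were mostly dim, with the exception of the neural marker MBP, whose highest signal was 1616. The median signal of their probe sets was between 9.88 and 28.3 for T cells, 13.8 and 33.5 for B cells, 16.9 and 40.2 for erythroid cells and megakaryocytes, 9.84 and 15.7 for fibroblasts and endothelium, 9.58 and 16.9 for epithelium and liver, and 14.5 and 36.4 for nerve and muscle. The highest signals of the other 5 lists were 189 (CD8A), 168 (CD79A), 142 (HBB), 299 (COL1A1) and 105 (APOA1).

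Pairs with the unstimulated array had more 2-fold differences in the median than pairs of stimulated arrays, though the ranges overlapped. Between 368 and 438 of 15374 genes were at least 2-fold apart in the 4 pairs that include it (median 376.5), against 197 to 373 in the 6 pairs of stimulated arrays (median 276). After quantile normalization the pairs with the unstimulated array had 350, 430, 344 and 331, and leukotriene C4 had 364 with leukotriene B4, 345 with lipoxin A4 and 316 with lipoxin B4, so these lay about as far apart. Control probe sets for ribosomal RNA, which enter no comparison, were dimmest on the unstimulated array and brightest on the leukotriene C4 array: the middle probe set of 18S rRNA was 4.78-fold, 15.7-fold, 1.91-fold and 5.58-fold over the unstimulated array with leukotrienes B4 and C4 and lipoxins A4 and B4. Simulated unchanged arrays gave a mean of 256.8 genes per comparison, and 286.8 was the highest mean of a simulation over its 4 comparisons, not the highest single comparison. Their residuals were pooled over the stimulated arrays, so the 256.8 is an average and does not hold for each comparison. Pairs of stimulated arrays that include leukotriene C4 had 330 to 373 genes 2-fold apart, and the others 197 to 222. Most such genes were dim: the SD of log2 differences between stimulated arrays was 0.43 for genes with a mean signal under 100 and 0.50 between 100 and 200, but 0.21 between 500 and 2000 and 0.17 above 2000. Among the 7097 genes over a signal of 500, 1 gene was higher and 12 lower with leukotriene B4, 4 and 9 with leukotriene C4, 0 and 3 with lipoxin A4, and 3 and 11 with lipoxin B4. With a floor set by the markers of other cell types (a signal of 92.1), 15 to 31 genes were at least 2-fold higher and 46 to 58 lower for each compound.

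**Figure D1:**
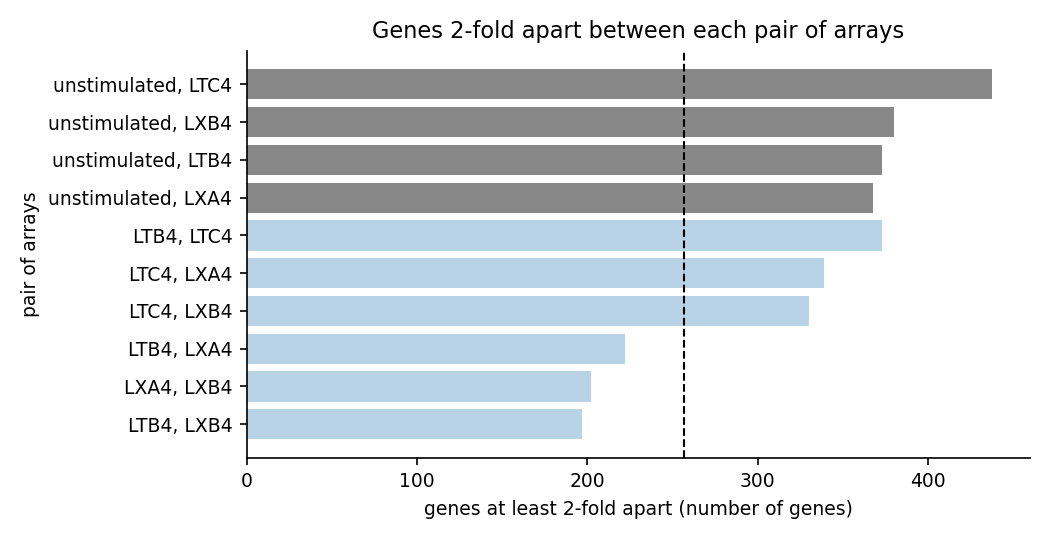
Number of genes at least 2-fold apart (x axis) for each of the 10 pairs of arrays (y axis; LTB4 and LTC4, leukotrienes B4 and C4; LXA4 and LXB4, lipoxins A4 and B4); grey bars are pairs with the unstimulated array, blue bars pairs of stimulated arrays, and the dashed line the mean of simulated unchanged arrays (256.8). The 4 grey bars lie between 368 and 438, and the blue bars between 197 and 373.

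For leukotriene B4 against unstimulated cells, the largest difference above the floor was in UTS2R, the urotensin 2 receptor (chromosome 17), with signals of 61.1 and 380 (log2 -2.64). NAT14, a putative acetyltransferase, was among the brighter genes and was lower at 551 against 1796 (-1.70). It was also lower with leukotriene C4 (-1.34), lipoxin A4 (-0.40) and lipoxin B4 (-1.37), so its difference was not particular to leukotriene B4. RNF208 (118 against 424), MROH6 (103 against 383) and CRY2, a repressor of the circadian clock (51.0 against 160), were also lower, with NEURL1, SNORA78 and SPDEF, whose other 3 probe sets gave 0.00 to -1.98. CRY2 was lower with leukotriene C4 (-0.32), lipoxin A4 (-1.72) and lipoxin B4 (-1.34) as well. CLDN19, a tight junction protein, was at least 5.62-fold lower, with its other 2 probe sets lower by log2 differences of -0.88 and -1.26; PCDHAC1 and GLDN were at least 2.30-fold and 2.14-fold lower. Higher genes were dimmer: SIGLEC5, an inhibitory sialic acid receptor of myeloid cells (173 against 59.6, log2 1.53), the kinase MAST3 (370 against 136), FLT1, a receptor of vascular endothelial growth factor (147 against 54.4; other probe sets 0.00 to 0.68), PPP1R13L, an inhibitor of p53 (157 against 56.7), and the vasopressin receptor AVPR1B (145 against 53.7). With leukotriene C4 and lipoxins A4 and B4, SIGLEC5 was higher as well (1.11, 0.46 and 0.85). So were MAST3 (0.98, 0.87 and 0.66) and PPP1R13L (1.19, 0.63 and 1.24), so these differences were not particular to leukotriene B4. FLT1 had 0.07, 0.82 and 0.32, and AVPR1B had -0.14 on each of these arrays. In all, 108 genes were at least 2-fold higher and 265 lower.

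Of the fixed lists, the oxidase, granule and protease genes of phagocytes were lower with leukotriene B4: 15 of 22 members were below 0, with a median of -0.07 at percentile 0.73 of matched random lists. No member was 2-fold apart. The same list had 0.06 with leukotriene C4 (percentile 11.1, with 13 of 22 above 0) and -0.08 with lipoxin B4 (percentile 3.91). After quantile normalization its median with leukotriene C4 turned to -0.05 (percentile 2.94). With leukotriene B4 and lipoxins A4 and B4 it was then -0.09, -0.11 and -0.05 (percentiles 1.2, 0.09 and 6.45). After quantile normalization the median was thus below 0 on all 4 arrays against the shared unstimulated array, and not with leukotriene B4 alone. Before it, the median with leukotriene C4 was above 0. The percentile lay under 2.5 in both settings with leukotriene B4 and lipoxin A4 only. The ribosomal protein genes had a median of -0.03 with leukotriene B4 (percentile 0.47; 19 of 24 below 0), which lay at percentile 23.8 among lists of the nearest genes by signal. Among list members, the NF-kappaB subunit RELB was lower (125 against 281, log2 -1.17), as was the costimulatory molecule CD80 (54.9 against 119, -1.12), whose other probe set gave -0.17. DPEP2, a dipeptidase that converts leukotriene D4 to E4, was at least 2.08-fold higher, and the interferon-induced GTPase MX1 at least 2.17-fold higher. The NF-kappaB list as a whole had a median of -0.02 (percentile 27.0), and the pro-inflammatory cytokines 0.02 (percentile 64.2).

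With leukotriene C4, ENPP2 differed by 8.71 times the spread between stimulated arrays at its signal, the most among the genes named by rank for this compound. Its signal was 1833 against 424 in unstimulated cells (log2 2.11), and its other measured probe set gave 1.83. ENPP2 (chromosome 8) encodes autotaxin, the secreted enzyme that makes lysophosphatidic acid. On the other 3 stimulated arrays ENPP2 lay between 396 and 460. The monocyte chemoattractant CCL2 was higher as well, at 1807 against 769 (log2 1.23), and lay between 727 and 777 on the other stimulated arrays. CCL20, the ligand of CCR6, was at least 3.29-fold higher. The haem oxygenase HMOX1 was higher at 210 against 95.3 (1.14), the prostaglandin E2 receptor PTGER1 at least 2.23-fold higher and MX1, under the floor in unstimulated cells, at least 2-fold higher.

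Other genes higher with leukotriene C4 were the phospholipase PLB1 (315 against 71.7, log2 2.13), KYNU, a hydrolase of the kynurenine pathway (192 against 58.1; other probe set 0.00), the inositol trisphosphate kinase ITPKC (144 against 48.7), CASTOR2, a homologue of the arginine sensor of mTORC1 (593 against 169), CCDC88B, LINC02985 and BAHCC1. C6orf52 was at least 2.16-fold higher. Lower genes included CROCC, a protein of the ciliary rootlet (53.9 against 204, -1.92; other probe sets 0.00 and -0.50), NHSL3 (70.2 against 243), the DNA polymerase POLL (61.7 against 188), LRRC43 (123 against 365; other probe set 0.00), RNF208 (132 against 424), MROH6 (134 against 383), LOC100505915 and LINC03124. The antiviral sensor OAS3 was lower at 64.1 against 171 (-1.41). In all, 184 genes were higher and 254 lower (42.0% higher), against 214 and 216 (49.8% higher) after quantile normalization. The NRF2 targets had the highest list median with this compound, 0.20 (percentile 94.4; 10 of 13 members above 0); the chemokines had 0.10 (percentile 90.5) and the pro-inflammatory cytokines 0.03 (percentile 44.2).

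**Figure D2:**
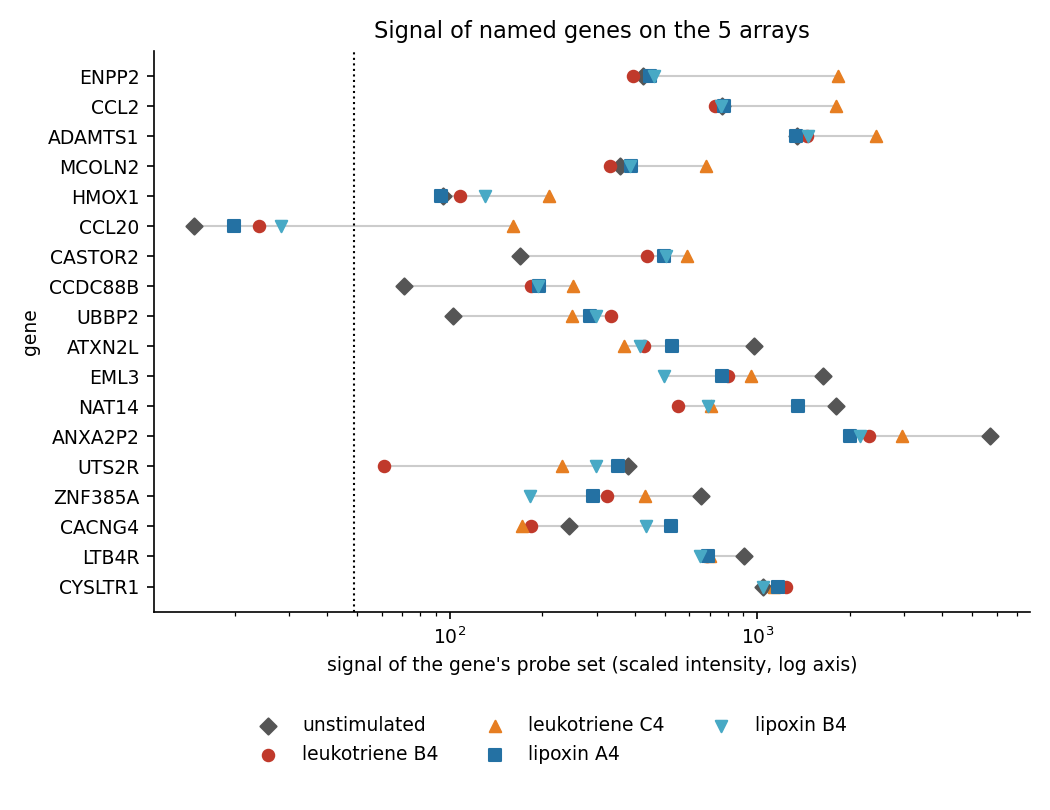
Signal (x axis, log scale, scaled intensity) of 18 genes named in the text (y axis) on the 5 arrays, 1 symbol per array; the dotted line is the floor (48.7) and grey lines span the arrays. ENPP2, CCL2 and CCL20 are brightest on the leukotriene C4 array, and CASTOR2, CCDC88B and UBBP2 are dimmest on the unstimulated array.

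Lipoxin A4 gave its largest difference above the floor in SPDEF, an ETS transcription factor (66.5 against 234, log2 -1.81), which was also lower with leukotriene B4 (-1.72); its other 3 probe sets gave 0.00 to -0.85 with lipoxin A4. CEBPE, a transcription factor of granulocyte maturation, was lower at 78.2 against 240 (-1.62), as were the neurotrophic factor receptor CNTFR (71.1 against 233), CCM2L (92.7 against 289), the metalloprotease ADAM33 (109 against 316), RNF122 and PTPDC1. SLC11A1, the phagosomal metal transporter of macrophages, was at least 7.13-fold lower on its brightest probe set (under the floor, against 347), while its other 2 measured probe sets gave -0.59 and -1.27; KIFC3 was at least 2.01-fold lower. ANXA2P2, a processed pseudogene, was lower at 1996 against 5708 (-1.52), while its parent gene ANXA2 had 13974 against 13757; the copies share sequence, so the value of the pseudogene is uncertain. KLHL36, a ubiquitin ligase adaptor, was higher (573 against 191, 1.59), with smaller differences of 0.21 and 0.33 on its other probe sets, as were FAM219A (198 against 66.9), the membrane protein POPDC1 (153 against 59.8) and FUT8-AS1. MCF2L was at least 2.58-fold higher, and among its other 3 probe sets the smallest and largest differences by size were -0.13 and 1.28.

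Of the lists, the oxidase, granule and protease genes had a median of -0.08 with lipoxin A4 (percentile 0.14; 15 of 22 members below 0). The ribosomal protein genes had -0.09 (percentile 0.00), at percentile 0.66 among lists of the nearest genes by signal, whose own median was -0.06. PLA2G4C, a cytosolic phospholipase A2, was lower (91.6 against 206, -1.17), and the immediate early gene NR4A1 was at least 2.25-fold higher on its brightest probe set, with its others between -0.29 and 0.63. In all, 108 genes were higher and 260 lower, so 29.3% of the counted genes were higher; after quantile normalization the counts were 151 and 193 (43.9% higher).

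With lipoxin B4, ZNF385A, a zinc finger protein that binds p53, was lower at 183 against 658 (log2 -1.85), and EML3, a microtubule-binding protein, at 496 against 1641 (-1.73, other probe set -0.87). EML3 was also lower on the other stimulated arrays (765 to 954), so its difference was not particular to lipoxin B4. ZNF135 (49.7 against 204, -2.03), the testis antigen FATE1 (52.1 against 180), WNT16, a secreted Wnt ligand (50.3 against 171), CD8A (56.3 against 187), TIAF1 and LOC100505915 were also lower. Higher genes were ZNF684 (173 against 59.7, 1.53; other probe set 0.28), ZNF319 (187 against 65.5), the microfibril protein MFAP2 (207 against 73.8), MIA2, which takes part in cargo export from the endoplasmic reticulum (419 against 158; other probe set 0.00), and the transcription factor TFAP2C (184 against 71.5). OAS3 was at least 3.50-fold lower, while MX1 was at least 2.17-fold and NR4A1 at least 2.19-fold higher; the other probe sets of NR4A1 lay between -0.71 and 0.00. TRAF1 (64.0 against 130, -1.02) and CD80 (58.7 against 119, -1.02) were lower, and the other probe set of each gave 0.00 and -0.17.

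Several lists lay low on the lipoxin B4 array. The NF-kappaB targets had a median of -0.16 (percentile 1.02; 11 of 18 members below 0), the immediate early genes -0.14 (percentile 1.24; 13 of 21), the anti-inflammatory and feedback genes -0.13 (percentile 1.63; 13 of 19) and the genes of cholesterol and fatty acid synthesis -0.13 (percentile 0.40; 10 of 18). After quantile normalization these percentiles were 0.30, 1.78, 5.88 and 4.23. The ribosomal protein genes had -0.40 (percentile 0.00; 24 of 24 below 0), at percentile 6.02 among lists of the nearest genes by signal; the bacterial cre control, added to every sample, was lower by -0.40 on the same array. Among markers of other cell types, those of fibroblasts and endothelium also lay low, with a median of -0.42 over 6 measured genes (percentile 1.95; 2.52 after quantile normalization); on the other arrays their percentile was between 15.7 and 89.96. In all, 78 genes were higher and 302 lower (20.5% higher), against 136 and 195 (41.1% higher) after quantile normalization.

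The rest of the 20 lists stayed clear of the outer 2.5% at either end of the random lists on all 4 arrays before quantile normalization. Their medians ranged from -0.06 to 0.06 for eicosanoid synthesis and breakdown, -0.29 to 0.00 for eicosanoid and formyl peptide receptors, 0.00 to 0.05 for interferon-stimulated genes, -0.02 to 0.02 for LXR and PPAR targets and 0.04 to 0.17 for heat shock proteins. They ranged from 0.01 to 0.12 for the unfolded protein and amino acid stress response, 0.04 to 0.09 for cell cycle and DNA replication, -0.06 to 0.14 for the mitochondrial respiratory chain, 0.04 to 0.18 for p53 targets and apoptosis, and -0.06 to 0.04 for monocyte and macrophage markers. The markers of the other 5 cell types had percentiles between 33.8 and 96.0. Over the 20 lists and 4 arrays, 9 of 80 percentiles lay in the outer 2.5% at either end, all low. By chance 4 would on average. After quantile normalization there were 5, and 4 lay there in both. The 80 values are not independent, since all comparisons share the unstimulated array and some lists share genes. The 9 include the ribosomal protein genes with leukotriene B4, lipoxin A4 and lipoxin B4, for which matching by deciles was too coarse. Whether 9 is an excess over 4 therefore cannot be judged. After quantile normalization the median of the respiratory chain genes on the lipoxin B4 array was 0.07 in place of -0.06, and that of the heat shock proteins was 0.14 in place of 0.04, at percentile 98.2.

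**Figure D3:**
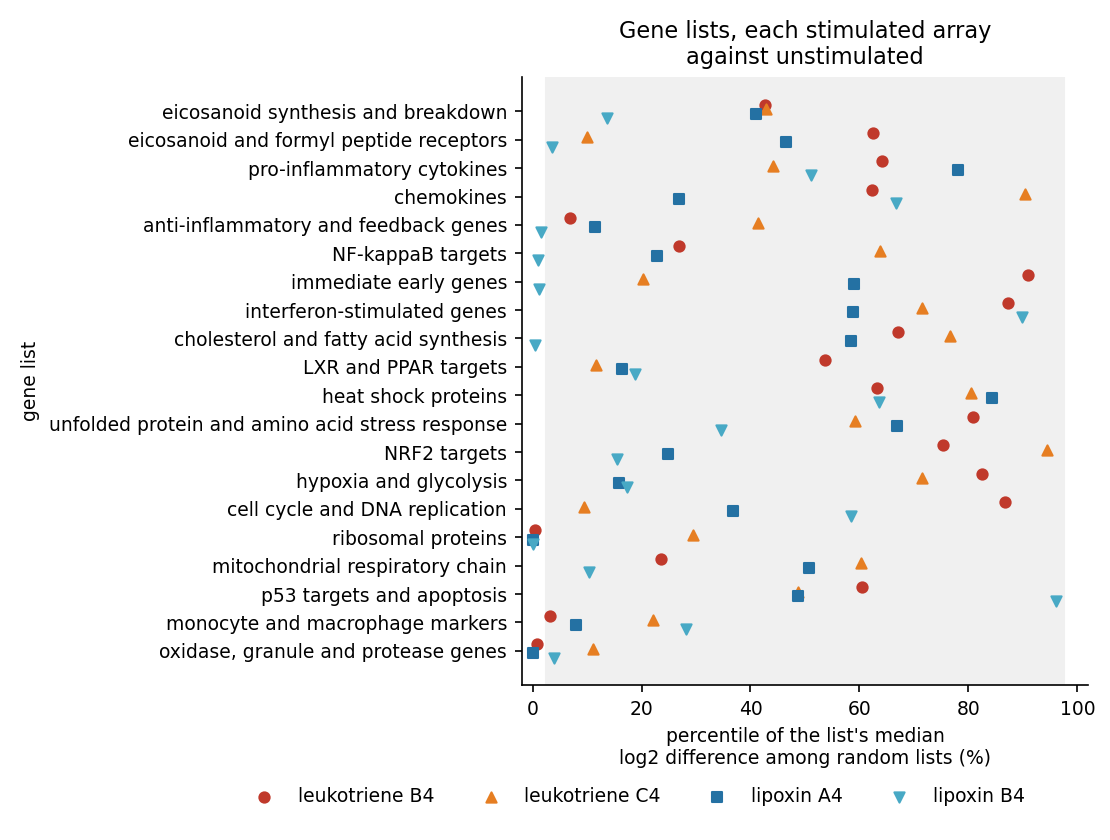
Percentile (x axis, %) of the median log2 difference of each of 20 gene lists (y axis) among 10000 random lists matched on signal, for each stimulated array against the unstimulated array; the shaded band leaves out 2.5% at either end. The 9 points outside the band all lie on the low side, 5 of them on the lipoxin B4 array.

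The 4 genes CASTOR2, CCDC88B, UBBP2 and IKBKB-DT were at least 2-fold higher with all 4 eicosanoids. CASTOR2 was between 439 and 593 on the stimulated arrays against 169, CCDC88B, a regulator of leukocyte trafficking, between 184 and 252 against 70.9, the pseudogene UBBP2, a near copy of a ubiquitin gene and so uncertain, between 250 and 334 against 103, and IKBKB-DT between 130 and 201 against 63.7. WNT16 (50.3 to 81.7 against 171) and RNF122, a ubiquitin ligase (57.2 to 81.9 against 170), were lower with all 4. In all, 11 genes were higher and 36 lower on every stimulated array, against 16 and 23 after quantile normalization and 3 and 1 with the background floor. Whether the unstimulated cells received the DMSO that carried the compounds is not given in the sources used here, so compound and vehicle are not separated in these genes. The same count with another array in the place of the unstimulated one gave 12 higher and 8 lower for leukotriene B4, 13 and 33 for leukotriene C4, 15 and 10 for lipoxin A4, and 14 and 1 for lipoxin B4, so the count for the leukotriene C4 array (46 together) was close to that for the unstimulated array (47). With the background floor the unstimulated, leukotriene C4 and lipoxin A4 arrays had 4 such genes each, leukotriene B4 3 and lipoxin B4 1. The ribosomal RNA controls were also dimmest on the unstimulated array and brightest on the leukotriene C4 array. Simulated unchanged arrays gave means of 7.82 higher and 9.70 lower, and at most 18 and 16. All simulated arrays had the same pooled residuals, and the 33 lower genes for the leukotriene C4 array also lay above 16. The simulated counts are thus no bound for a single array, and the 36 lower genes cannot be judged by them.

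Log2 differences from the unstimulated array correlated between the eicosanoids across genes, which are not independent replicates, with Pearson r from 0.56 (leukotrienes B4 and C4) to 0.66 (leukotriene B4 and lipoxin B4). Sharing 1 unstimulated array alone gave r of 0.50 in the simulations. The covariances were between 0.08 and 0.09 against 0.05 simulated. Leukotriene B4 and lipoxin B4 shared 30 higher and 132 lower genes, where simulated unchanged arrays shared 27.3 and 38.4 and independent lists would share 0.55 and 5.21; leukotrienes B4 and C4 shared 32 and 96, against 27.3 and 38.6 simulated and 1.29 and 4.38 if independent. The 2 lipoxins shared 25 and 127, against 27.7 and 38.7 simulated and 0.55 and 5.11 if independent. With 1 unstimulated array the control cannot be split. The simulations gave it the pooled residuals of the stimulated arrays, so a control with a wider spread is not covered. Part or all of the excess may come from it.

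Leukotriene B4 and leukotriene C4, which unlike leukotriene B4 carries glutathione, were compared at the same dose and time. ENPP2 was lower with leukotriene B4 (396 against 1833, log2 -2.21; other probe set -2.01), and so were the homeobox gene ANHX (72.4 against 284), LINC02450 (73.7 against 287), UTS2R (61.1 against 231), the kinesin KIF26B (59.0 against 204), the meiotic protein IHO1 (57.2 against 180), the riboflavin transporter SLC52A3 (57.2 against 169) and CMTM5. CEACAM3, a phagocytic receptor of granulocytes, was at least 2.94-fold, HLA-DOA at least 2.29-fold and the scavenger receptor STAB1 at least 2.02-fold lower with leukotriene B4. On their other probe sets the smallest and largest differences by size were 0.16 and -1.03, 0.00 and -1.12, and 0.00 and -1.77. HLA-DOA was higher with leukotriene B4 when probe sets that may cross-hybridise were left out. TTC38 was higher with leukotriene B4 (287 against 59.7, 2.26; other probe set 0.72), as were the lipid transfer protein STARD5 (159 against 48.8), POM121L12 (other probe set 0.00), DAGLA, a diacylglycerol lipase that makes the endocannabinoid 2-AG (145 against 50.8), POLL and the peptide hormone UCN3. In all, 373 genes (2.43%) were at least 2-fold apart, 133 higher and 240 lower with leukotriene B4, the most of any pair of stimulated arrays.

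Lipoxins A4 and B4 are positional isomers that differ in where a hydroxyl group sits. The metallothionein MT1G was higher with lipoxin A4 (226 against 56.1, log2 2.01), as were the defensin DEFB124 (265 against 81.0), CD8A (169 against 56.3), the phosphodiesterase subunit PDE6G (234 against 83.2), the endocytic receptor LRP1 (175 against 64.0, 1.45; other probe set 1.77), BMERB1, TPSD1 and SPECC1 (other probe set 0.37). LILRB1, an inhibitory receptor for class I HLA, was at least 2.22-fold and MCF2L at least 2.58-fold higher with lipoxin A4. CCM2L was lower with lipoxin A4 (92.7 against 329, -1.83), as were HROB, a factor of DNA repair (58.1 against 161), PTPDC1 (49.2 against 130), GNB1L (78.5 against 204; other probe sets 0.00 and -0.80) and CNTFR (71.1 against 178). In all, 202 genes (1.31%) were at least 2-fold apart, 126 higher and 76 lower with lipoxin A4. Both this number and the 373 for the leukotrienes lack a replicate error, so neither pair is shown to act alike or apart.

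Between the classes, the calcium channel subunit CACNG4 had the widest gap: 184 and 172 with the leukotrienes against 523 and 436 with the lipoxins. Its other measured probe set gave 0.00. ZC3H6 (100 and 107 against 239 and 205; other probe set -0.22), AIFM3, MROH6, MAP3K2-DT and UTS2R were also lower with the leukotrienes, and RNF227 (110 and 123 against 49.3 and 64.3), the proprotein convertase PCSK7 (355 and 622 against 169 and 281; other probe set 0.18), PLB1 and PTPDC1 were higher. The hypoxia and glycolysis genes were higher with the leukotrienes, with a median of 0.17 (percentile 100; 18 of 22 members above 0) and 0.11 (percentile 99.97) after quantile normalization. Among lists of the nearest genes by signal, the percentile of 99.89 became 91.09 without the leukotriene C4 array (median 0.08) and 91.05 without the lipoxin B4 array (median 0.09). After quantile normalization the median was 0.05 in both cases, at percentiles of 97.81 and 93.64. Of 2 members chosen after their values were seen, the hexokinase HK2 had 2595 and 2172 against 1972 and 2050, and the lactate dehydrogenase LDHA 32140 and 36644 against 30280 and 23976. The other 2 probe sets of HK2 did not show this order. LDHA had -0.35 on the lipoxin B4 array, where the genes nearest in signal to the ribosomal protein genes, about as bright, also had a median of -0.35. The ribosomal protein genes had 0.29 (percentile 100, and 98.88 among lists of the nearest genes by signal). After quantile normalization, which nearly fixes values this bright, they had 0.02 (percentile 77.4). The LXR and PPAR targets had 0.11 (percentile 97.6, and 80.1 after quantile normalization). Markers of fibroblasts and endothelium were also higher with the leukotrienes, with a median of 0.25 (percentile 98.06; 98.58 after quantile normalization), and those of epithelium and liver lay at 95.3 (97.8). In all, 29 genes were higher and 16 lower with the leukotrienes, 45 together, against 22 and 27 after quantile normalization and 1 and 5 with the background floor, so the balance of directions was not stable. The other 2 ways of pairing the stimulated arrays separated 48 and 53 genes.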

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

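The finer matching of random lists, the comparison of the leukotriene C4 genes with other arrays, the other limits for bright probe sets and the allowance for the choice of the gap, and all tests of the hypoxia and glycolysis genes were chosen after the result was seen, and the matching by deciles before. The shuffling of gene names was planned before its shares were seen, but with the counts of genes and their limits in view, and its number was raised from 1000 to 10000 after first shares of 1.3% for the leukotriene C4 array and 4.4% for the unstimulated array.

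Control probe sets for ribosomal RNA, which enter no comparison, were brighter on every stimulated array. The probe set at the 3' end of 18S rRNA had a deposited signal of 13000 in unstimulated cells against 37810 with leukotriene B4, 42213 with leukotriene C4, 24168 with lipoxin A4 and 27548 with lipoxin B4. The probe set at the 5' end of 28S rRNA had 662 against 2017, 2855, 1274 and 2248. The middle probe set of 18S rRNA was 4.78-fold, 15.7-fold, 1.91-fold and 5.58-fold over the unstimulated array in the same order, and that at the 5' end 3.56-fold, 13.3-fold, 1.60-fold and 4.55-fold. The ratio of the 3' to the 5' probe set of GAPDH lay between 0.996 and 1.06 on the 5 arrays.

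The following genes are among those named above for the gap between the classes, so their order by class was selected for. In them both leukotrienes lay on 1 side of the unstimulated array and both lipoxins on the other. For 1 compound each, PTPDC1 and MAP3K2-DT were nearly level with the unstimulated array. None of these differences was tested. RNF227 had log2 differences of 0.44 and 0.61 with leukotrienes B4 and C4 and -0.71 and -0.33 with lipoxins A4 and B4. PCSK7 had 0.23 and 1.04 against -0.84 and -0.11, and PTPDC1 0.0208 and 0.665 against -1.54 and -0.14. CACNG4 had -0.41 and -0.50 against 1.10 and 0.838, and MAP3K2-DT -0.95 and -0.72 against 0.0631 and 0.34.

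The hypoxia and glycolysis genes had medians of 0.0775 and 0.127 with leukotrienes B4 and C4 and of -0.00482 and -0.0271 with lipoxins A4 and B4, a difference that was not tested against replicates. This is 1 of 20 lists, of which 3 lay in the outer 2.5% at either end between the classes, as did 1 of the 6 lists of other cell types (fibroblast and endothelial markers, percentile 98.06). After quantile normalization the ribosomal protein genes lay at percentile 77.4 and the LXR and PPAR targets at 80.1, both no longer in the outer 2.5%. Among lists of the nearest genes by signal the percentile was 99.97 after quantile normalization. The same value with matching by deciles was part of the result that was flagged. The outcome was thus known beforehand, and it does not decide whether dimming of bright probe sets on the lipoxin B4 array plays a part. The difference rests in good part on the lipoxin B4 and leukotriene C4 arrays: the percentile was 91.05 without the first and 91.09 without the second, against 99.75 without leukotriene B4 and 99.57 without lipoxin A4, and after quantile normalization 93.64, 97.81, 99.12 and 99.97 in the same order. The other 2 ways of pairing the arrays gave percentiles of 88.08 and 6.82, so neither stood out as the class pairing did, but with 3 pairings the class of the compound cannot be told apart from a grouping by chance.

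On the leukotriene C4 array 4 genes lay outside all other arrays on each of at least 2 bright probe sets, by a log2 gap of at least 0.35: ENPP2, MCOLN2 and ADAMTS1 were higher and HLCS lower. Noise on single probe sets as the whole cause is argued against: 0.79% of 10000 shuffles of gene names over probe sets gave as many genes, and with the lowest share over 5 gaps taken in every shuffle, 0.04% to 0.83% of shuffles had one as low at 4 limits of signal. Single limits were less clear, with 5.45% at a gap of 0.30 and 7.8% at a gap of 0.50, where 1 gene was left. Probe sets that share sequence would share noise, which the shuffles leave out. The shuffles also take no account of signal, with which the spread between arrays falls, so the shares may be too low. The unstimulated array also had 4 such genes (3.74% of shuffles, 0.05% to 22.2% at other single limits, and 0.02% to 0.97% with the choice of the gap allowed for). The lipoxin B4 array had 5, and at gaps of 0.25 and 0.30 it had 31 and 17, the most of any array. Of the 5, ACTB, TUBA1C and RPS4X are very bright, so a difference in the RNA or labelling of a whole array stays open, as does a response to leukotriene C4. The gap of ENPP2 was 1.55 against at most 0.64 for the other genes of this kind.

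The ribosomal protein genes had a median of -0.40 on the lipoxin B4 array, at percentile 0.0 among lists matched by deciles of signal, which was set beforehand as the value that would exclude dimming of the brightest probe sets. That matching was too coarse to decide: the genes of those deciles had a median signal of 7515 against 35132 for the list. Among lists of the nearest genes, with a median signal of 30582, the percentile was 6.02 and the lists' own median -0.35, and the bacterial cre control was lower by -0.40, which is consistent with dimming of all very bright probe sets. Lower abundance of these mRNAs cannot be told apart from it, since the list lay below its nearest neighbours by less than 2 SD of their medians; how such a value would be read was settled after it was seen. Quantile normalization nearly fixes values at the top of the range and decides nothing here.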

How the results depend on the processing

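Quantile normalization combined with the background floor, the matching of lists to the nearest genes and other limits for bright probe sets, whose values stand beside that result, were chosen after seeing the data. Counts below are for leukotriene B4 higher and lower, leukotriene C4 higher and lower, lipoxin A4 higher and lower, lipoxin B4 higher and lower, all 4 higher and lower, leukotrienes over lipoxins higher and lower, leukotriene B4 against C4, and lipoxin A4 against B4. The lower floor gave 907, 1461, 1219, 1351, 902, 1466, 671, 1626, 105, 297, 518, 272, 2386 and 1842 genes. The higher floor gave 3, 18, 6, 15, 4, 5, 4, 17, 0, 0, 0, 0, 10 and 2. The background floor gave 15, 55, 31, 52, 17, 46, 18, 58, 3, 1, 1, 5, 67 and 31. A 3-fold threshold gave 6, 29, 24, 24, 9, 23, 8, 31, 1, 0, 0, 1, 42 and 15. Dim genes enter or leave with the floor, so signal over background limits every count. Quantile normalization with the background floor gave 18, 53, 40, 51, 20, 41, 26 and 47 for the first 8. Quantile normalization alone moved lipoxin B4 to 136 and 195, the genes lower with all 4 to 23, those lower with leukotrienes to 27 and the outer list percentiles to 5; the mean of all probe sets moved those higher with leukotrienes to 18. The cause of these moves was not tested. The median pair with the unstimulated array had 2368, 21 and 73 genes under the lower, higher and background floors, and the median pair of stimulated arrays 2182, 8.5 and 48.5. Using the values as deposited, or only genes whose probe sets share 1 sign, moved no count by over 1.5 times. The mean correlation between compounds, 0.61, lay between 0.57 and 0.63 under the alternatives. HLA-DOA reversed to 0.37 between leukotrienes B4 and C4 without probe sets that may cross-hybridise, since other probe sets then represent it. Of 124 values of named genes, 122 were at least 2-fold with the same sign after quantile normalization, 123 as deposited, 71 with the background floor, 124 with the lower floor, 103 with the mean of all probe sets and 95 without cross-hybridising ones, where 25 were not measured; with the higher floor 11 were, and 78 were not measured. Of 100 list medians, 70 moved by less than the spread of random lists after quantile normalization, 82 as deposited and 57 without cross-hybridising probe sets. With lists matched to the nearest genes, 7 of 80 percentiles lay in the outer 2.5% at either end, 4 of them also after quantile normalization.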

Other observations

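The tests of the classes and of the excess of lower genes were chosen after the result was seen, and the genes named here were picked after their values were seen.

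Beyond the genes named by rank, ATXN2L, a component of stress granules, had a signal of 975 in unstimulated cells and between 368 and 527 on the stimulated arrays, with both of its bright probe sets outside the others. USB1, an exonuclease that trims U6 RNA, had 619 against 303 to 409. On the leukotriene C4 array the metalloprotease ADAMTS1 had 2432 against 1335 to 1463 on the others, and the endolysosomal channel MCOLN2 679 against 331 to 388, while HLCS, which attaches biotin to carboxylases, had 140 against 204 to 244. MTERF2, a mitochondrial protein, had 127 on the lipoxin A4 array against 173 to 247. On the lipoxin B4 array TUBA1C, ACTB, EP400, PLA2G6 and RPS4X were all lower than elsewhere, by log2 differences from the mean of the others between -0.40 and -0.55. Of these, ACTB, TUBA1C and RPS4X had signals between 28288 and 55668 on the other arrays, whereas EP400 (293 on the lipoxin B4 array) and PLA2G6 (141) were far dimmer. The bright cre control was lower by -0.40 on the lipoxin B4 array too, and lists of genes nearest in signal to the ribosomal protein genes had a median of -0.35. As many genes came from 0.36% of shuffles, which take no account of signal. With a gap of 0.40 in place of 0.35 the array had 0 such genes. With gaps of 0.25 and 0.30 it had 31 and 17, the most of any array, and 0% of shuffles gave as many.

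The hypothesis that the class of the compound sets the largest division among the stimulated arrays was not borne out. Leukotrienes and lipoxins were separated by 45 genes, and the other pairings of the 4 arrays by 48 and 53; after quantile normalization the numbers were 49, 47 and 55.

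Before quantile normalization more of the counted genes were lower than higher for each compound; after it this still held, by less, with 128 higher and 222 lower for leukotriene B4, 214 and 216 for leukotriene C4, 151 and 193 for lipoxin A4 and 136 and 195 for lipoxin B4. With each array in turn as the reference, the mean share of lower genes was 69.8% for the unstimulated array, 43.7% for leukotriene B4, 61.1% for leukotriene C4, 44.0% for lipoxin A4 and 31.45% for lipoxin B4. After quantile normalization the shares were 57.2%, 40.2%, 55.9%, 49.9% and 46.8%. Scaling that leaves dim probe sets brighter on the unstimulated array was to bring its share under 55% after quantile normalization. The 57.2% found lies within 1 SD of that bound (SD 5.52 over the 4 comparisons), so how far scaling accounts for the excess stays open. All 4 comparisons share the unstimulated array, so this SD holds none of the error of that array and is not the error of the mean. The margin of 1 SD was set after the value was seen. Read without it, 57.2% lies over the bound and argues against scaling as the whole cause. Chance differences of the shared unstimulated array cannot be told apart from a response either, since 1 of the 5 arrays has the highest share in any case and the next highest was 61.1%.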
